A study of Mus musculus with 17 samples.

How the data were processed

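Pancreatic islets of 2-month-old mice were measured on 17 Affymetrix whole-transcript arrays in 5 groups. The groups are wt (3 arrays), RIP-Cre (3), Men1 RIP-Cre (3), Rbp2 RIP-Cre (4) and Men1 Rbp2 RIP-Cre (4). Groups were read from the sample titles, and every array was used. The titles number the arrays of a group as repeats and do not say that they are separate animals.

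The values deposited by the authors are log2 intensities, 1 per probe set, for 35512 probe sets. The labels name biotin-labelled single-stranded DNA, and the software, background correction and normalization are not given in the sources used here. The log base was read from the values: 82.3% of the values between 0 and 3 lie at log2 of whole multiples of 0.25, against 9.03% of all values with 2 decimals in that range. No array was a copy of another, since the smallest root mean square difference between any 2 arrays was 0.220. Intensities of this kind carry no counts, so the number of arrays limits the precision.

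Probe sets were joined to gene symbols with the platform's gene table. Of the 35512 probe sets, 21789 named exactly 1 gene, 1621 named several and 12102 were not in the table. For 21698 of the single-gene probe sets the gene was found in the reference annotation. Each gene was represented by its probe set with the highest mean over all arrays, which gave 19938 genes, 999 of which had more than 1 probe set. Ins1 had no probe set that names it alone and was not analysed here.

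Group means were fitted to all 17 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. The comparisons were RIP-Cre against wt, each knockout against RIP-Cre, the double knockout against each single knockout, and the interaction, which is the Rbp2 effect in Men1 knockouts minus the Rbp2 effect in RIP-Cre. A gene was called when its Benjamini-Hochberg adjusted p from limma was under 0.05 within the comparison. Slopes through 0 of one effect on another were fitted across called genes, with an error from leaving out arrays, and were repeated with genes and effects taken from different arrays.

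A total of 403 members of 25 gene lists were chosen, of which 370 were tested. The lists were targeted genes, beta cell identity and function, other islet endocrine cells, exocytosis and granule, genes usually silent in beta cells, CDK inhibitors, cell cycle, Hox genes, H3K4 methylation machinery, oxidative phosphorylation, lactogen response, unfolded protein response, early response to isolation, interferon response, cholesterol synthesis, acinar cells, duct cells, endothelial cells, mesenchymal cells, macrophages, lymphocytes, Schwann cells, red blood cells, adipocytes and sex-linked genes. Lists were tested with camera, preset correlation 0.01, and adjusted over the 25 lists of a comparison. The camera test was repeated with an estimated correlation, and the list mean per array was tested with an exact two-sided permutation test. The shift of a list is its mean log2 fold change minus the mean of the other genes. Members were also counted after adjustment over the list alone.

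Apart from those under Other observations, the genes named in the text follow a rule. Men1 and Kdm5a are named in every comparison, and Ins2, Gcg, Sst, Ppy, Cdkn1b and Cdkn2c in comparisons with RIP-Cre. In each comparison the 10 called genes with the highest and the 10 with the lowest log2 fold change are named. Predicted or clone-named genes, olfactory and vomeronasal receptors, microRNAs and small nucleolar RNAs were left out by symbol pattern and counted. Of each list, up to 2 members with the highest and 2 with the lowest moderated t are named, and sex-linked genes serve as a check of the samples. Groups, comparisons, tests, the 25 lists, the naming rule and a first set of alternatives were chosen before the data were examined.

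That first set of alternatives used wt, or wt and RIP-Cre pooled, as the control, or only the arrays of the groups compared. It also used the repeat number as a block, a filter at the 25th percentile of mean level, all probe sets, quantile normalization, an intensity trend with robust variances, other probe sets of a gene, and each array left out in turn. The array mean of the acinar list and the difference of Xist and Y-linked genes were each used as a covariate. Chosen after seeing the data were cyclic loess normalization, the array median as a covariate, leaving out 3 control arrays with high medians (wt 1, wt 3 and RIP-Cre 3), the lymphocyte mean as a covariate, and slopes from different arrays. The permutation test of list means and a list of 40 imprinted genes were also added after seeing the data.

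The procedure was tested on simulated data made from the spread of these arrays, in 19938 genes per comparison. Genes were drawn independently, with the same spread in all groups and no array-wide shift. The real arrays do not have these properties, so the shares below apply only to data of that kind. Between 4 and 8 of the other genes were called per comparison. In Men1 RIP-Cre against RIP-Cre, 94.0% of genes changed by 1 on the log2 scale were called, and 43.3% of those changed by 0.5. In RIP-Cre against wt the shares were 88.1% and 28.4%, in Rbp2 RIP-Cre against RIP-Cre 98.5% and 46.3%, and in the double knockout against RIP-Cre 97.0% and 46.3%. In the double knockout against Men1 RIP-Cre they were 94.0% and 35.8%, and against Rbp2 RIP-Cre 95.5% and 46.3%. For genes called in both single knockouts, which share the RIP-Cre arrays, 100 sets of unchanged groups were simulated. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Raw intensity files were not used here, and probe sets with no gene or several genes entered only the alternative with all probe sets.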

Results

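Expression was measured in pancreatic islets of 2-month-old mice on 17 arrays. The RIP-Cre transgene makes Cre recombinase under the rat insulin promoter, so that floxed genes are removed in beta cells. Men1 codes for menin, a tumour suppressor of endocrine tissue that works with enzymes that methylate histone H3 at lysine 4. Rbp2 is the demethylase that removes this mark, and its gene is now named Kdm5a. The 17 arrays are 3 of wt mice, 3 of RIP-Cre mice, 3 of Men1 RIP-Cre mice, 4 of Rbp2 RIP-Cre mice and 4 of Men1 Rbp2 RIP-Cre mice, called the double knockout. The comparisons ask what loss of each gene changes and whether loss of Rbp2 alters the effect of Men1 loss. Since the labels do not say that arrays are separate animals, p-values measure the spread between these arrays. Values are log2 intensities, and adjusted p-values of genes are from limma.

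Men1 was lower in every Men1 knockout array than in every other array. It lay between 8.14 and 8.43 in the 3 Men1 RIP-Cre arrays and between 8.46 and 8.87 in the 4 double-knockout arrays. The ranges were 9.25 to 9.45 in wt and 9.31 to 9.49 in RIP-Cre. Against RIP-Cre the log2 fold change was -1.06 (SE 0.11, adjusted p = 3.08e-05) in Men1 RIP-Cre and -0.77 (adjusted p = 0.000558) in the double knockout. In Rbp2 RIP-Cre islets Men1 rose by 0.73 (SE 0.11, adjusted p = 0.00359), and its 4 arrays, between 10.05 and 10.24, lay above each of the other 13. Kdm5a did not pass in any comparison. Its mean was 9.24 in wt, 9.26 in RIP-Cre, 9.44 in Men1 RIP-Cre, 9.04 in Rbp2 RIP-Cre and 9.24 in the double knockout, and its change in Rbp2 RIP-Cre against RIP-Cre was -0.22 (adjusted p = 0.148). A probe set outside the deleted part of a gene checks nothing about the deletion, and where the Kdm5a probes lie was not analysed here. The silencer of the inactive X chromosome, Xist, was low on all 17 arrays (5.73 to 6.23), and the Y-linked demethylase gene Kdm5d lay between 8.90 and 9.31. The other Y-linked genes were not equal between groups: Uty rose by 0.88 (adjusted p = 0.000821) and Eif2s3y by 0.53 (adjusted p = 0.0037) in Men1 RIP-Cre against RIP-Cre. With low Xist and Y-linked signal on all 17 arrays, no array read as female, so these differences are not differences in sex.

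**Figure D1:**
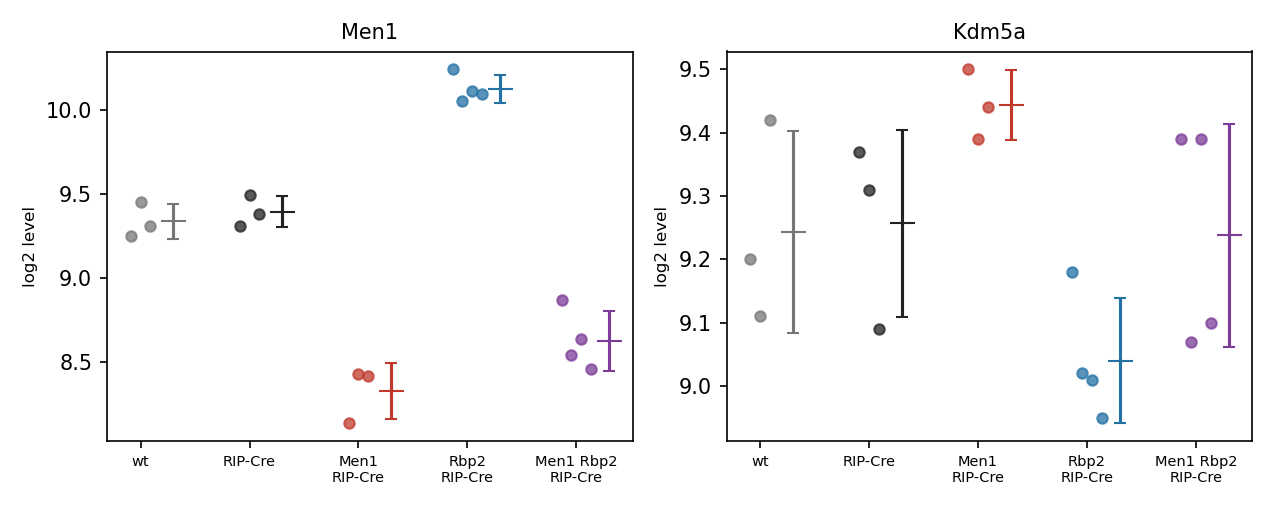
Level of Men1 and Kdm5a (log2) on each array by group; points are arrays, and the bar beside them is the group mean with its SD. Men1 is lowest in the 7 arrays of the Men1 knockout groups and highest in the 4 Rbp2 RIP-Cre arrays.

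Knockout groups differed from RIP-Cre in a way that depended on the level. Most genes were lower at low levels and higher at the highest. At a mean level of 9.11 the medians were near 0, at 0.01 in Men1 RIP-Cre, 0.03 in Rbp2 RIP-Cre and 0.01 in the double knockout. The median of the tested genes lay between 7.97 and 8.16 on RIP-Cre arrays and between 7.99 and 8.10 on wt arrays. It was 7.86 to 7.87 on Men1 RIP-Cre, 7.82 to 7.98 on Rbp2 RIP-Cre and 7.88 to 7.95 on double-knockout arrays. The median log2 fold change of all genes was -0.23 in Men1 RIP-Cre, -0.13 in Rbp2 RIP-Cre and -0.15 in the double knockout, each against RIP-Cre, and 0.20 for the interaction. In Men1 RIP-Cre against RIP-Cre the median was -0.43 in the 10% of genes with the lowest level and 0.20 in the 10% with the highest. For Rbp2 RIP-Cre these medians were -0.27 and 0.18, and for the double knockout -0.30 and 0.21. The double knockout against Men1 RIP-Cre ran the other way, with 0.13 and -0.01. RIP-Cre against wt was flat, with 0.01 and 0.00. Cyclic loess normalization brought the medians to -0.02, -0.01, -0.01 and 0.01, so counts and called lists of each knockout against RIP-Cre are given below also after that step and with the array median held fixed.

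**Figure D2:**
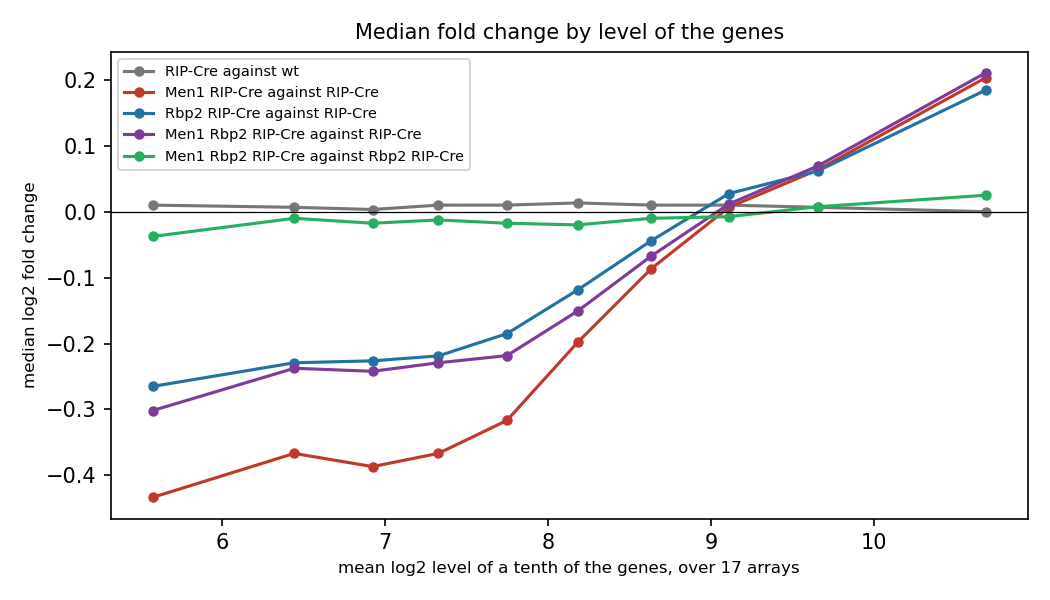
Median log2 fold change against mean log2 level for 10 bins of the 19938 genes by level, in 5 comparisons. The 3 knockout comparisons with RIP-Cre run from -0.43, -0.27 and -0.30 at the lowest levels to 0.20, 0.18 and 0.21 at the highest, while RIP-Cre against wt stays near 0.

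The Cre transgene alone changed no gene past the threshold. RIP-Cre against wt called 0 of 19938 genes with limma, and 552 had an unadjusted p under 0.05. The smallest p-values belonged to Aadac, a lipase of the endoplasmic reticulum (-0.55), Igkv6-20, an immunoglobulin segment (-1.13), and Trim12a, an antiviral ubiquitin ligase (-0.73), each with an adjusted p of 1. Men1 (0.06) and Kdm5a (0.01) did not pass. Without wt array 3, 26 genes were called, all lower.

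Small shifts of fixed lists were called between these groups at the preset correlation. Interferon response genes had a shift of -0.29 (adjusted p = 7.18e-07) and genes usually silent in beta cells -0.17 (adjusted p = 0.00014), each lower on 3 of 3 arrays than the wt mean. Cholesterol synthesis (0.15, adjusted p = 0.00201) and lactogen response (0.34, adjusted p = 0.0109) were higher on 3 of 3 arrays. Macrophages (-0.19, adjusted p = 0.0176) and lymphocytes (-0.26, adjusted p = 0.0428) were lower on 3 of 3, and the early response to isolation (-0.19, adjusted p = 0.0496) on 2 of 3. By the exact two-sided permutation test the smallest p of the 7 was 0.1, for lactogen response, and the others ran from 0.2 to 0.7. No member of any list passed over all genes, and all 7 calls were lost with an estimated correlation: adjusted p = 0.275 for interferon response, silent genes and lactogen response with an estimated correlation, adjusted p = 0.774 for cholesterol synthesis and macrophages, adjusted p = 0.847 for lymphocytes and adjusted p = 0.849 for the early response. Only the silent-gene call held without each array in turn. The lymphocyte shift turned to 0.07 without wt array 1, where the B cell receptor gene Cd79a stood at 8.08, and the interferon shift was -0.12 (adjusted p = 0.159) without wt array 2. Cholesterol synthesis fell to 0.04 (adjusted p = 0.485) without wt array 3, macrophages to -0.05 (adjusted p = 0.880) without wt array 1 and the early response to -0.03 (adjusted p = 0.640) without RIP-Cre array 2. The lactogen shift was 0.28 (adjusted p = 0.0569) without wt array 2.

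The genes that changed most with loss of Men1 came from several kinds of function. The highest rises were in Lrrc55, an accessory subunit of large-conductance potassium channels (2.68, SE 0.15, adjusted p = 4.55e-08), Slitrk6, a neuronal membrane protein (2.59), and Tceal6, an X-linked elongation-factor homologue (2.39). They were followed by the antimicrobial peptide gene Defb1 (2.28), the fatty acid desaturase gene Scd1 (2.22), the RNA-binding gene Rbm12b2 (2.16) and the uncharacterised AI593442 (2.06). The chaperone helper Dnajb9, the actin-binding Fam107a and the respiratory chain subunit Uqcrb each rose by 1.97. The lowest values belonged to H2-Eb1, a chain of MHC class II (-2.21), Eps8l2, an actin-linked receptor substrate (-2.11), the platelet chemokine Ppbp (-2.09) and the metalloprotease Adam25 (-2.02), which spread widely in RIP-Cre (6.12 ± 2.50 SD, n = 3) and was at 4.68 in wt. Prom1, a protein of membrane protrusions (-1.997), the guanylate cyclase receptor Gucy2c (-1.76), the long RNA Snhg11 (-1.69), the lipid kinase gene Pik3c2g (-1.68), the sodium channel gene Scn3a (-1.62) and Gem, a small GTPase that restrains calcium channels (-1.61), also fell. The adjusted p of these 20 genes ran up to 0.0302 for Adam25, and in all 20 the 3 Men1 arrays lay beyond the 3 RIP-Cre arrays, which chance gives in 10% of genes not picked by size of change, as these were, so the share sets no chance value for them.

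In numbers, limma called 10660 of 19938 genes in Men1 RIP-Cre against RIP-Cre, 3126 higher and 7534 lower, and 555 by at least 2-fold. Predicted genes, receptors of smell and small RNAs made up 1583 of them. After cyclic loess normalization 6875 were called, 3677 higher and 3198 lower, and 5448 were in the same direction as before. With the array median held fixed 396 were called, 212 higher and 184 lower, and 372 were shared. The difference of Xist and Y-linked genes (the sex-linked difference) held fixed left 114, 60 higher and 54 lower, 111 of them shared. No array read as female, so this fall does not come from a mix of sexes. With the array median held fixed the median size of change of the 10660 genes went from 0.51 (median SE 0.14) to 0.19 (median SE 0.15), so the calls ended because the changes shrank. Of the 20 named genes 18 stayed called after cyclic loess and 13 with the array median held fixed, where Adam25 turned to 0.14. Without RIP-Cre array 3, 6174 genes were called. Ppbp was lost without RIP-Cre array 2 (-1.06, adjusted p = 0.0931) and without Men1 array 1 (-1.96, adjusted p = 0.0570), and Adam25 without RIP-Cre array 3 (fell by 0.59, adjusted p = 0.0557) or any Men1 array.

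Among hormones, Ins2 (0.12), Gcg (-0.14), Sst (-0.32) and Ppy (0.16) did not pass. After cyclic loess normalization Ins2 stood at -0.41 and Ppy at -0.38, so no direction is given for them. The 4 hormones read between 12.92 and 14.23 on all arrays, where a probe set can be saturated, so the lack of a call says nothing about change in any comparison. The cyclin-dependent kinase inhibitor gene Cdkn2c rose by 0.45 (adjusted p = 0.0223). That call ended without RIP-Cre array 1 (Cdkn2c 0.38, adjusted p = 0.0748), RIP-Cre array 3 (Cdkn2c 0.35, adjusted p = 0.112) or Men1 array 3 (Cdkn2c 0.39, adjusted p = 0.0758). Cdkn1b did not pass on its main probe set (0.06), while another probe set of the gene, at a mean level of 7.92, read 1.33 and passed. The 2 probe sets differ, so no statement on Cdkn1b is made.

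Of the fixed lists, beta cell genes had a shift of 0.69 (adjusted p = 1.57e-09, and adjusted p = 0.616 with an estimated correlation) and 15 of 22 members rose. The glucose-6-phosphatase gene G6pc2 (1.35) and the incretin receptor gene Glp1r (1.29) led, while the sulfonylurea receptor gene Abcc8 (-0.07) and the insulin gene activator Mafa (-0.15) did not pass. Oxidative phosphorylation had a shift of 0.62 (adjusted p = 5.44e-13, and adjusted p = 0.616 with an estimated correlation), with 29 of 52 members higher, such as Cox6c (1.17) and Atp5j (1.32), and 2 lower, Ndufb7 (-0.49) and Ndufa7 (-0.35). Cholesterol synthesis had 0.60 (adjusted p = 6.04e-05, and adjusted p = 0.616 with an estimated correlation), with 9 of 15 higher, among them the sterol sensor partner Insig1 (0.83) and the demethylating enzyme Nsdhl (0.76). In exocytosis and granule (0.37, adjusted p = 0.0331, and adjusted p = 0.616 with an estimated correlation) 7 of 16 rose, such as the granin Scg2 (1.01) and the fusion protein gene Snap25 (1.10), and 3 fell, including Stx1a (-0.79) and the priming factor Unc13a (-0.51). The call on exocytosis ended without RIP-Cre array 3 (0.27, adjusted p = 0.0955) and without Men1 array 2 (0.35, adjusted p = 0.0577). In the unfolded protein response (0.44, adjusted p = 0.00557, and adjusted p = 0.662 with an estimated correlation) 10 of 19 rose, including the chaperone Hspa5 (0.72), and 2 fell, the death-linked factor Ddit3 (-0.60) and the kinase regulator Trib3 (-0.26). Hox genes, patterning factors that menin keeps active in other tissues, had a shift of -0.35 (adjusted p = 0.000243, and adjusted p = 0.729 with an estimated correlation), and 32 of 37 fell, such as Hoxa5 (-0.66) and Hoxb13 (-0.62). Members called over the list alone were the same in number for all 6. The mean of each of the 6 lists moved on 3 of 3 arrays beyond the 3 RIP-Cre arrays, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows.

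These list shifts depended on the scaling. After cyclic loess normalization oxidative phosphorylation kept 0.34, cholesterol synthesis 0.44 and Hox genes -0.25 as calls, beta cell genes were at 0.19 and the unfolded protein response at 0.09 without a call, and exocytosis turned to -0.07. With the array median held fixed, beta cell genes were at 0.19, oxidative phosphorylation at 0.13 and cholesterol synthesis at 0.30, all called. Hox genes (-0.0088), exocytosis (0.04) and the unfolded protein response (0.0045) were not called there.

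No call was made on the remaining lists in Men1 RIP-Cre against RIP-Cre. Among other islet endocrine cells (shift -0.37, adjusted p = 0.148) 5 of 11 genes fell, such as the alpha cell factor Irx1 (-1.06) and the delta cell factor Hhex (-0.96). All 4 Schwann cell genes fell, such as Cdh19 (-1.25) and Sox10 (-0.63), with a shift of -0.61 (adjusted p = 0.0728). After cyclic loess normalization both lists were called, at -0.67 and -0.55. Macrophages (0.38, adjusted p = 0.0658) had 5 of 12 higher, such as the complement gene C1qc (0.47), and 2 lower, such as Mrc1 (-0.55). The H3K4 methylation machinery (0.23, adjusted p = 0.0658) had 5 higher, such as the demethylase Kdm1a (0.33) and the menin partner Jund (0.54), and 2 lower, Setd1b (-0.35) and Kmt2d (-0.31), of 15. The cell cycle list (0.14, adjusted p = 0.148) had 4 higher, such as Pcna (0.98) and Mcm4 (0.48), and 6 lower, such as the D-type cyclin gene Ccnd1 (-0.65). Shifts were 0.03 for CDK inhibitors, 0.07 for silent genes, 0.10 for lactogen response, -0.10 for the early response, -0.09 for interferon response, 0.18 for acinar cells and -0.25 for duct cells. They were -0.05 for endothelial cells, 0.04 for mesenchymal cells, -0.03 for lymphocytes, -0.28 for red blood cells, -0.24 for adipocytes, 0.44 for sex-linked genes and -0.29 for the targeted genes. In CDK inhibitors, silent genes, lactogen response, cell cycle and mesenchymal cells the shift was above 0 while the mean and median log2 fold change were below 0, and for lactogen response the direction of the test was also down. The acinar cell shift was 1.34 with the array median held fixed.

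The largest changes with loss of Rbp2 were also spread over unlike genes. Pcp4, a calmodulin regulator (1.89, SE 0.35, adjusted p = 0.00942), Dapl1, a death-associated protein homologue (1.76), the surface protein gene Msln (1.70), the secreted synaptic gene Lgi1 (1.62) and the membrane insertase gene Emc7 (1.44) rose most. They were followed by Dnajb9 (1.37), the thyroid hormone deiodinase gene Dio1, the G protein regulator Rgs2, the selenium carrier Selenop and the histone gene H2bc4, each at 1.31. The largest falls were in Gem (-1.87, SE 0.17, adjusted p = 9.62e-05), H2-Eb1 (-1.76), the RNA-editing enzyme gene Apobec1 (-1.60), the ribosomal RNA gene n-R5s136 (-1.59) and Rnu3a (-1.43), a small nucleolar RNA that the symbol pattern did not remove. Ankrd7 (-1.33), the lysophospholipase gene Gdpd3 (-1.29), the long RNA Snhg17 (-1.13), Lrmda (-1.08) and the retinol dehydrogenase gene Rdh13 (-1.08) came next. Other probe sets of Snhg17 read -1.60 and -0.12, so the size of its fall depends on the probe set. In 18 of the 20 the 4 Rbp2 arrays lay beyond the 3 RIP-Cre arrays, the exceptions being Ankrd7 and Gdpd3. Chance gives this in 5.71% of genes not picked by size of change, which is no chance value for these.

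Limma called 2672 genes in Rbp2 RIP-Cre against RIP-Cre, 1336 higher and 1336 lower, 76 by at least 2-fold, and 313 were predicted genes and others left unnamed. After cyclic loess normalization 1879 were called, 1119 higher and 760 lower, 1387 of them shared. With the array median held fixed 42 were called, 32 higher and 10 lower, 41 of them shared, and the median size of change of the 2672 genes went from 0.49 (median SE 0.13) to 0.29 (median SE 0.13). The sex-linked difference held fixed left 85, 58 higher and 27 lower. Of the 20 named genes 18 stayed called after cyclic loess and 3 with the array median held fixed. Counts depended on single arrays: 223 without RIP-Cre array 3, 353 without Rbp2 array 1 and 920 without Rbp2 array 2. Leaving out each array in turn kept 9 of the 20 named genes. Of the rest, Lgi1, H2bc4, Dnajb9, Rgs2, H2-Eb1, Ankrd7, Gdpd3, n-R5s136, Rnu3a and Snhg17 ended without RIP-Cre array 3, with adjusted p from 0.0537 for Lgi1 (1.55) to 0.176 for Dnajb9 (0.99). All of these but Lgi1 and H2bc4 also ended without Rbp2 array 1. Rgs2 ended without RIP-Cre array 2 too, Dnajb9 without Rbp2 array 2, and Ankrd7 without RIP-Cre array 2 or Rbp2 array 2 or 3. Gdpd3 was lost without any single array except Rbp2 array 2. Msln ended without RIP-Cre array 2 (1.35, adjusted p = 0.0511), Rbp2 array 1 (1.49, adjusted p = 0.0753) or Rbp2 array 2. Ins2 (0.04), Gcg (0.26), Sst (0.29), Ppy (0.40), Cdkn1b (0.13) and Cdkn2c (0.06) did not pass, and the first 5 turned below 0 after cyclic loess normalization.

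In Rbp2 RIP-Cre against RIP-Cre, shifts of 8 lists were called at the preset correlation only, and none with an estimated correlation. Oxidative phosphorylation had a shift of 0.54 (adjusted p = 1.46e-21), and 27 of 52 genes rose over all genes and 37 when adjusted over the list alone, led by Ndufa9 (0.94) and Ndufs6 (0.49). The unfolded protein response had a shift of 0.54 (adjusted p = 3.39e-07), with 11 of 19 higher, such as Hspa5 (0.84) and the asparagine synthetase gene Asns (0.73). For both, adjusted p = 0.550 with an estimated correlation. Cholesterol synthesis (0.44, adjusted p = 1.60e-05) had 5 of 15 higher, 7 adjusted over the list alone, such as Insig1 (0.82) and Msmo1 (0.71). Beta cell genes (0.34, adjusted p = 6.40e-06) had 5 of 22 higher, 7 adjusted over the list alone, with G6pc2 at 0.91 and Glp1r at 0.65. Endothelial cells (0.25, adjusted p = 0.00213) had 3 of 13 higher, 5 adjusted over the list alone, with the vascular growth factor receptors Flt1 (0.41) and Kdr (0.40). Exocytosis and granule (0.23, adjusted p = 0.0428) had 2 of 16 higher and 1 lower, Stx1a (-0.47), and 5 and 2 adjusted over the list alone. For these 4 lists adjusted p = 0.654 with an estimated correlation. The early response to isolation (0.49, adjusted p = 0.00405, and adjusted p = 0.769 with an estimated correlation) had 1 of 15 higher, Btg2 (0.39), and 0 adjusted over the list alone. Hox genes (-0.23, adjusted p = 0.000748, and adjusted p = 0.777 with an estimated correlation) had 3 of 37 lower, 11 adjusted over the list alone, such as Hoxb7 (-0.70).

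Of these list means, oxidative phosphorylation, the unfolded protein response, cholesterol synthesis and exocytosis lay on 4 of 4 arrays above the 3 RIP-Cre arrays, with an exact two-sided permutation p of 0.0286, the smallest that 3 against 4 allows (0.143 adjusted). By the same exact permutation test, beta cell genes lay above on 3 of 4 (p = 0.0571), Hox genes below on 3 of 4 (p = 0.0857), endothelial cells above on 3 of 4 (p = 0.257) and the early response on 1 of 4 (p = 0.343). Cyclic loess normalization left oxidative phosphorylation at 0.34, the unfolded protein response at 0.28, cholesterol synthesis at 0.33 and Hox genes at -0.15 as calls, and turned beta cell genes to -0.04 and exocytosis to -0.10. Endothelial cells (0.12) and the early response (0.39) were then not called. Holding the array median fixed kept oxidative phosphorylation (0.23), the unfolded protein response (0.26), cholesterol synthesis (0.25), endothelial cells (0.27) and the early response (0.70) as calls. Beta cell genes and exocytosis (each 0.02) and Hox genes (-0.0074) were not called there. Single arrays ended 3 calls: exocytosis was at 0.13 (adjusted p = 0.410) without RIP-Cre array 3 and at 0.18 (adjusted p = 0.109) without Rbp2 array 1, endothelial cells at 0.20 (adjusted p = 0.0550) without RIP-Cre array 2, and the early response at 0.25 (adjusted p = 0.181) without Rbp2 array 3 and 0.34 (adjusted p = 0.0725) without RIP-Cre array 2. Within the cell cycle list, which was not called (-0.01), the D-type cyclin genes Ccnd1 (1.24, adjusted p = 0.00618) and Ccnd2 (0.72) rose while the mitotic kinase gene Plk1 (-0.73) and the replication factor gene Cdc6 (-0.51) fell.

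Some of the largest changes of each single knockout were also among those of the double knockout. These comparisons share the 3 RIP-Cre arrays, so a part of that may come from the controls. Lrrc55, the highest rise with Men1 loss, was at 7.08 in the double knockout against 7.09 in RIP-Cre. Against RIP-Cre, Slitrk6 and Defb1 (each 2.07), Tceal6 (1.99, SE 0.14, adjusted p = 2.31e-06), Pcp4 (1.82) and Lgi1 (1.78) rose. So did the potassium channel gene Kcnh5 (1.77), the membrane gene Tmem255a (1.72), the kinase substrate Marcks (1.70), the transferrin receptor gene Tfrc (1.68) and the glycosyltransferase gene C1galt1 (1.68). The lowest were the spliceosomal RNA Rnu6 (-3.02, at a low mean of 3.83 in RIP-Cre), Ppbp (-1.88), Adam25 (-1.83), the vault RNA Vaultrc5 (-1.66), Gdpd3 (-1.60), Gem (-1.59), Rnu3a (-1.56), Apobec1 (-1.54), n-R5s136 (-1.51) and Ankrd7 (-1.495). In 18 of the 20 the groups did not overlap, the exceptions being Ppbp and Adam25, and the 5.71% that chance gives for unpicked genes sets no chance value here.

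Limma called 6716 genes in the double knockout against RIP-Cre, 2600 higher and 4116 lower, 245 by at least 2-fold, and 854 were left unnamed by the rule. After cyclic loess normalization 5048 were called, 2779 higher and 2269 lower, 3878 of them shared. With the array median held fixed 280 were called, 172 higher and 108 lower, 257 of them shared, and the median size of change of the 6716 went from 0.46 to 0.24 (median SE 0.13 in both). The sex-linked difference held fixed left 2131, 1165 higher and 966 lower. Of the 20 named genes 18 stayed called after cyclic loess and 9 with the array median held fixed. The count was 2371 without RIP-Cre array 3, 3958 without double-knockout array 2 and 3619 without array 4. Ppbp was lost without RIP-Cre array 2 (fell by 0.85, adjusted p = 0.173) or 3 and without double-knockout arrays 1, 2 or 4. Adam25 was lost without RIP-Cre array 3 (fell by 0.40, adjusted p = 0.209) or any double-knockout array, and n-R5s136 without RIP-Cre array 3. Ins2 (0.08), Gcg (0.11), Sst (0.05), Ppy (0.44), Cdkn1b (-0.02) and Cdkn2c (0.23) did not pass, and the hormones turned below 0 after cyclic loess normalization.

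Oxidative phosphorylation had a shift of 0.61 in the double knockout against RIP-Cre (adjusted p = 6.41e-19), with 34 of 52 genes higher, 39 adjusted over the list alone, such as Ndufa9 (0.86) and Sdhd (0.70). Beta cell genes (0.51, adjusted p = 1.28e-08) had 14 of 22 higher, 15 adjusted over the list alone, with Glp1r and G6pc2 each at 1.16. Cholesterol synthesis (0.56, adjusted p = 5.29e-06) had 9 of 15 higher, such as Idi1 (0.96). The cell cycle list (0.26, adjusted p = 0.000128) had 8 of 41 higher, 7 adjusted over the list alone, such as Pcna (1.03) and Mcm4 (0.56). Other calls were the unfolded protein response (0.38, adjusted p = 0.00158; 10 higher and 1 lower of 19), macrophages (0.38, adjusted p = 0.0178; 5 higher and 1 lower of 12, with C1qb at 0.80) and Schwann cells (-0.50, adjusted p = 0.0480; 4 of 4 lower, with Cdh19 at -0.90). For these 7 lists adjusted p = 0.578 with an estimated correlation. Hox genes (-0.30, adjusted p = 0.000204, and adjusted p = 0.587 with an estimated correlation) had 19 of 37 lower, 22 adjusted over the list alone. List means lay on 4 of 4 arrays beyond the 3 RIP-Cre arrays, except cell cycle and the unfolded protein response, each on 3 of 4. The exact two-sided permutation p was 0.0286 (0.102 adjusted) for beta cell genes, oxidative phosphorylation, Hox genes, macrophages and Schwann cells, 0.0571 for cholesterol synthesis, 0.0857 for the unfolded protein response and 0.114 for cell cycle. The calls kept after cyclic loess normalization were oxidative phosphorylation (0.39), cholesterol synthesis (0.44), cell cycle (0.30), Hox genes (-0.22), macrophages (0.43) and Schwann cells (-0.46), while beta cell genes (0.08) and the unfolded protein response (0.09) were lost. Holding the array median fixed kept oxidative phosphorylation (0.26), beta cell genes (0.16), cholesterol synthesis (0.35), cell cycle (0.25) and macrophages (0.38) as calls. The unfolded protein response (0.07), Hox genes (-0.05) and Schwann cells (-0.23) were not called there. The macrophage call ended without double-knockout array 1 (0.30, adjusted p = 0.0644), and the Schwann cell call without RIP-Cre array 1 (-0.54, adjusted p = 0.0534), double-knockout array 1 (-0.52, adjusted p = 0.0741) or array 3 (-0.51, adjusted p = 0.0580).

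**Figure D3:**
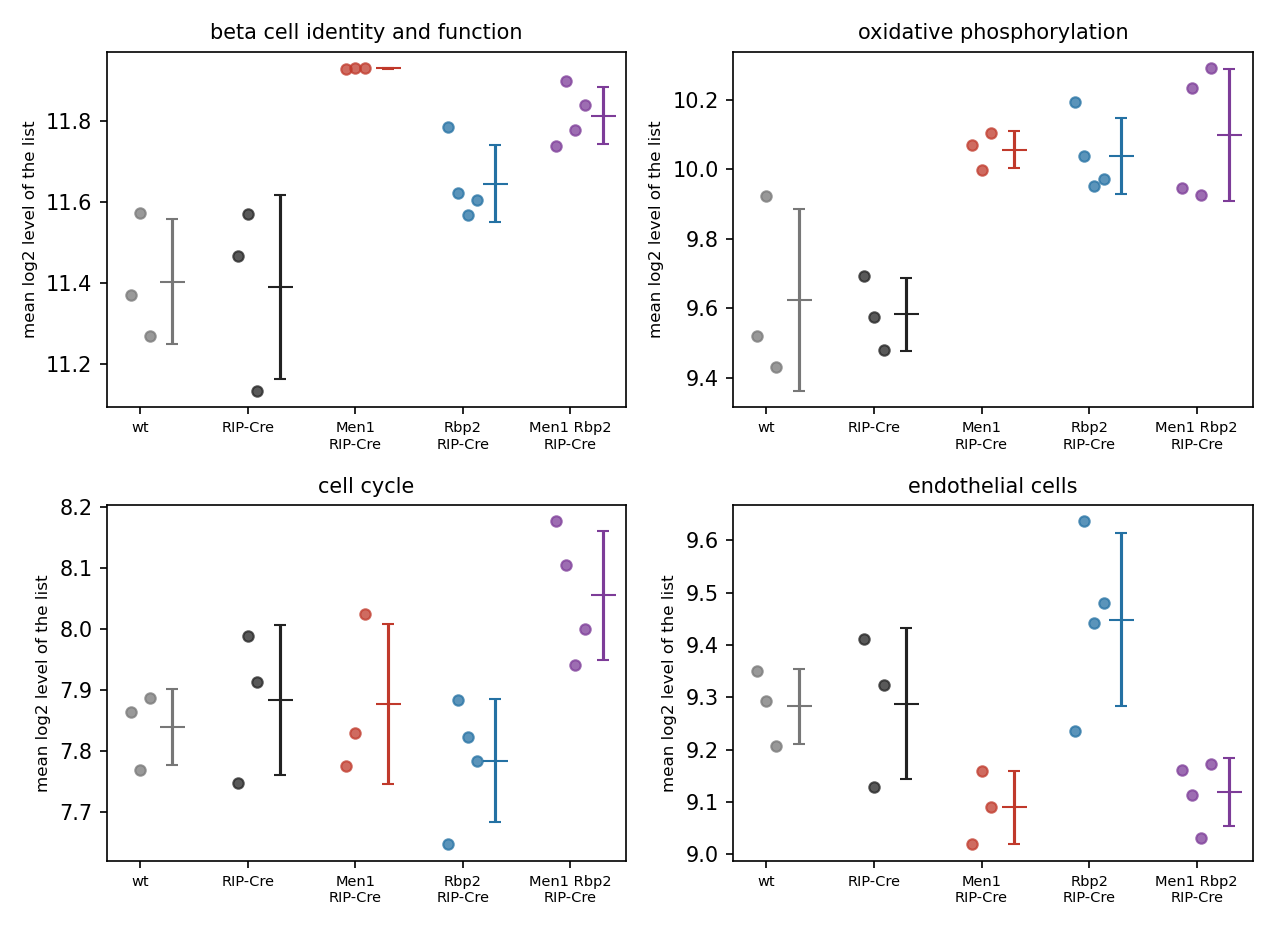
Mean log2 level of 4 gene lists on each array by group; points are arrays, and the bar beside them is the group mean with its SD. The cell cycle mean lies between 7.94 and 8.18 on the 4 double-knockout arrays and between 7.65 and 7.88 on the 4 Rbp2 RIP-Cre arrays, and the endothelial mean between 9.03 and 9.17 and between 9.24 and 9.64.

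Men1 loss and Rbp2 loss moved many of the same genes in comparisons that share the 3 RIP-Cre arrays. Gem and H2-Eb1 were among the strongest falls of both, and Dnajb9 among the rises. Of the genes called in both, 2119 had the same direction and 42 the opposite one. Independent lists of these sizes would share 209 higher and 505 lower genes, 714 in all. Unchanged groups simulated against the same controls shared 0 called genes on average over 100 draws, a value that leaves out the effects and so sets no expectation for the overlap. The effects correlated across genes with r = 0.754 against a simulated 0.442, with a covariance of 0.105 against 0.0115, and genes are not independent replicates. With wt as the control of Rbp2 RIP-Cre 1224 genes were shared. Part of the overlap may come from the shared controls, which are too few to be split. The overlap was 1301 after cyclic loess normalization and 9 with the array median held fixed. It was 122 without RIP-Cre array 3, 254 and 710 without Rbp2 arrays 1 and 2, and 1403 and 1406 without Men1 arrays 1 and 3.

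Loss of Rbp2 was also compared on the Men1 RIP-Cre background. Against Men1 RIP-Cre, the double knockout was higher in the kinetochore gene Spc25 (2.54, SE 0.22, adjusted p = 1.29e-05), Dapl1 (2.24), Prom1 (1.88), Pcp4 (1.87), the islet potassium channel gene Kcnk16 (1.84) and the tight junction gene Cldn4 (1.80). It was also higher in Msln (1.72), Eps8l2 (1.68), Dio1 (1.57) and the calcium-binding gene Cib3 (1.44). It was lower in Gdpd3 (-2.84), Lrrc55 (-2.70, SE 0.14, adjusted p = 1.47e-08), Fam107a (-1.73), the zinc finger gene Zfp868 (-1.56), the secreted Angptl7 (-1.52), the phosphatase subunit gene Ppp2r2c (-1.45), the cytokine receptor gene Cntfr (-1.22), the steroid dehydrogenase gene Hsd3b2 (-1.21), the glycine receptor gene Glra1 (-1.19) and Lonrf2 (-1.19). In all 20 the groups did not overlap, which chance gives in 5.71% of genes not picked by size of change, so this adds nothing to their p-values. Men1 itself (0.30, adjusted p = 0.205) and Kdm5a (-0.21, adjusted p = 0.399) did not pass.

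This comparison called 333 genes, 220 higher and 113 lower, 48 by at least 2-fold, with 7 left unnamed by the rule. Cyclic loess normalization gave 463, 238 higher and 225 lower, 305 of them shared, and moved the share of higher genes from 66.1% to 51.4%. The array median held fixed gave 454, of which 312 were shared, and the median size of change stayed at 0.59 against 0.60. The sex-linked difference held fixed gave 111, 69 higher and 42 lower. The count was also 111 without Men1 array 1, 176 without Men1 array 3 and 211 without double-knockout array 1. Of the 20 named genes 17 were called without each array in turn. Pcp4 was lost without Men1 array 1 (1.74, adjusted p = 0.0681) or 3, Cntfr without Men1 array 1 (-1.13, adjusted p = 0.0638), and Msln without Men1 array 1 (1.45, adjusted p = 0.280) or 3 or double-knockout array 1, 2 or 3. Of the lists, other islet endocrine cells were higher (0.37, adjusted p = 0.00351, and adjusted p = 0.977 with an estimated correlation), with 0 of 11 called over all genes by limma and 3 adjusted over the list alone, led by the transthyretin gene Ttr (0.92, adjusted p = 0.0504). Beta cell genes were lower (-0.17, adjusted p = 0.00444) with 0 of 22 called, a shift that turned to 0.11 with the sex-linked difference held fixed, and the cell cycle list higher (0.12, adjusted p = 0.0133) with 1 of 41 called, Ccnd1 (1.38, adjusted p = 0.00142). For both, adjusted p = 0.994 with an estimated correlation. The first 2 list means lay on 4 of 4 arrays beyond the 3 Men1 arrays and cell cycle on 2 of 4, with an exact two-sided permutation p of 0.0571 for the first 2 and 0.143 for cell cycle. The cell cycle call ended without Men1 array 1 (0.08, adjusted p = 0.136) or 2 (0.10, adjusted p = 0.125) and without double-knockout array 1 (0.09, adjusted p = 0.143) or 2 (0.11, adjusted p = 0.112).

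**Figure D4:**
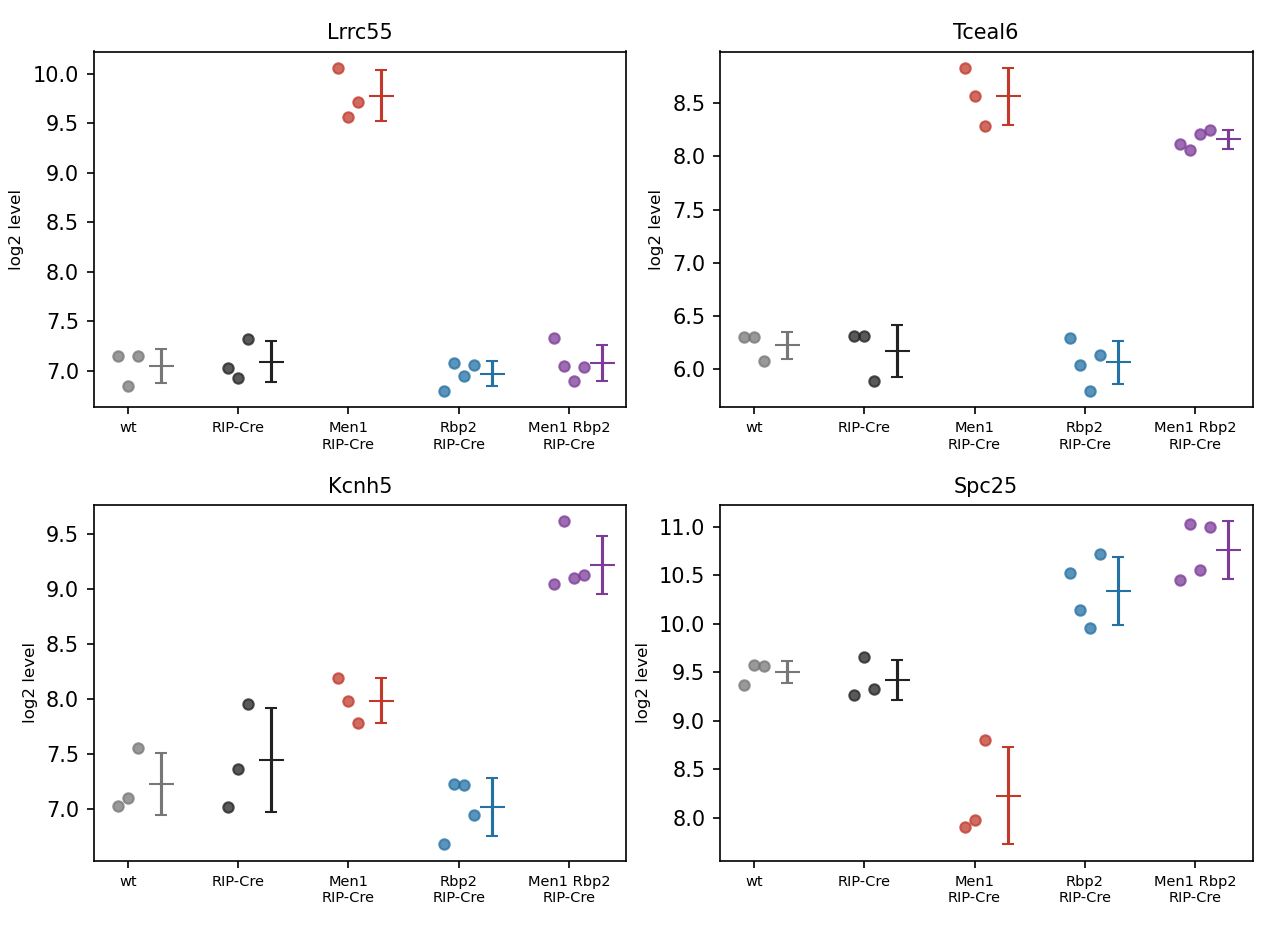
Level of Lrrc55, Tceal6, Kcnh5 and Spc25 (log2) on each array by group; points are arrays, and the bar beside them is the group mean with its SD. Lrrc55 is at 9.56 to 10.06 in Men1 RIP-Cre alone, Tceal6 is high in both Men1 knockout groups, and Kcnh5 is highest in the double knockout.

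Loss of Men1 was also compared on the Rbp2 RIP-Cre background. Against Rbp2 RIP-Cre, the double knockout was higher in Kcnh5 (2.20), Tceal6 (2.10, SE 0.13, adjusted p = 3.20e-07), the imprinted membrane protein gene Nnat (1.60), AI593442 (1.5), the neuronal gene Slitrk1 (1.27) and Kirrel3os (1.23). It was also higher in the neuronal GTPase gene Rit2 (1.14), the clock repressor Nr1d1 (1.09), the motor protein gene Myo7a (1.05) and the phosphatase gene Ptprs (1.03). The falls were Men1 (-1.495, SE 0.10, adjusted p = 3.80e-07), the sarcoglycan gene Sgcd (-1.48), Tcf24 (-1.34), the peptidase gene Anpep (-1.23), Otoa (-1.17), the exchange factor gene Rasgrf2 (-1.13), the imprinted insulin receptor adaptor Grb10 (-1.12), the calcium-binding Necab2 (-1.06), Gucy2c (-1.06) and the oxytocin receptor gene Oxtr (-0.94). In all 20 the groups did not overlap, which chance gives in 2.86% of genes not picked by size of change, so here too it adds nothing. Kdm5a did not pass (0.20, adjusted p = 0.476).

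Limma called 239 genes here, 116 higher and 123 lower, 19 by at least 2-fold, with 2 left unnamed by the rule. Cyclic loess normalization gave 360, 188 higher and 172 lower, 225 of them shared, and the array median held fixed gave 510, among them all 239. Counts fell to 109, 132 and 137 without Rbp2 arrays 2, 3 and 4, and to 130, 159 and 133 without double-knockout arrays 2, 3 and 4. Of the 20 named genes all but Ptprs, Gucy2c and Oxtr were called without each array in turn. Without Rbp2 array 2 they stood at 0.86 (adjusted p = 0.0995), -1.03 (adjusted p = 0.0648) and -0.83 (adjusted p = 0.145). Without Rbp2 array 3 or double-knockout array 1 or 3 all 3 were lost as well, Ptprs and Oxtr without double-knockout array 4, Oxtr without array 2, and Gucy2c without Rbp2 array 4.

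In the double knockout against Rbp2 RIP-Cre, shifts of the cell cycle and endothelial lists were called at the preset correlation only, with 1 member of each called. The cell cycle list had a shift of 0.28 (adjusted p = 1.04e-14), with 1 of 41 genes higher over all genes, the replication helicase gene Mcm3 (0.43, adjusted p = 0.0388), and 20 higher and 1 lower adjusted over the list alone. The topoisomerase gene Top2a (0.62, adjusted p = 0.0614) did not pass over all genes. The endothelial list had a shift of -0.32 (adjusted p = 9.83e-11), with 1 of 13 lower, the receptor gene Tie1 (-0.41, adjusted p = 0.0142), and 9 lower adjusted over the list alone. For both, adjusted p = 0.251 with an estimated correlation. Both means lay on 4 of 4 arrays beyond the 4 Rbp2 arrays, with an exact two-sided permutation p of 0.0286 (0.179 adjusted), the smallest that 4 against 4 allows. Both calls held without each array in turn and under cyclic loess normalization, at 0.28 and -0.33.

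Shifts of 9 further lists were called in the same comparison. The early response to isolation was at -0.48 (adjusted p = 3.13e-05), beta cell genes at 0.17 (adjusted p = 0.000173, with 5 higher and 1 lower adjusted over the list alone), macrophages at 0.27 (adjusted p = 0.00199, also 5 and 1), other islet endocrine cells at -0.23 (adjusted p = 0.0129) and Schwann cells at -0.26 (adjusted p = 0.0454). For these 5, adjusted p = 0.556 with an estimated correlation. The unfolded protein response was at -0.16 (adjusted p = 0.0202, and adjusted p = 0.649 with an estimated correlation), the targeted genes at -0.64 (adjusted p = 0.0294, and adjusted p = 0.339 with an estimated correlation), lymphocytes at 0.34 (adjusted p = 0.0301, and adjusted p = 0.657 with an estimated correlation) and acinar cells at 0.42 (adjusted p = 0.0304, and adjusted p = 0.810 with an estimated correlation). Apart from Men1, 0 members of these 9 lists were called over all genes by limma. Macrophages lay on 4 of 4 double-knockout arrays above the Rbp2 arrays. The acinar shift turned to -0.03 without double-knockout array 3, where the carboxypeptidase gene Cpa1 stood at 11.66. Lymphocytes were at 0.11 (adjusted p = 0.568) without double-knockout array 1, other islet endocrine cells at -0.14 (adjusted p = 0.137) without double-knockout array 3 and -0.18 (adjusted p = 0.108) without Rbp2 array 1, and the unfolded protein response at -0.09 (adjusted p = 0.247) without double-knockout array 1. Without Rbp2 array 1 the acinar call (0.31, adjusted p = 0.108), the lymphocyte call (0.30, adjusted p = 0.136) and the unfolded protein response call (-0.12, adjusted p = 0.183) also ended. Schwann cells were lost without any of 5 arrays, down to -0.21 (adjusted p = 0.153) without Rbp2 array 3, and the targeted genes without Rbp2 array 1 (-0.57, adjusted p = 0.109).

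The interaction asks whether the effect of losing both genes differs from the sum of the single effects. It was above 0 in H2-Eb1 (2.91), Prom1 and Myo7a (each 1.92), Gem (1.89), the long RNA AI506816 (1.88), Eps8l2 (1.85), Trim12a (1.67), Kcnh5 (1.66), Spc25 (1.62) and the peptide hormone gene Apela (1.60). It was below 0 in Lrrc55 (-2.58, SE 0.19, adjusted p = 6.41e-06), Zfp868 (-1.90), the cilium gene Ttc30b (-1.87), the vesicle protein gene Cd63 (-1.82), Tmtc3 (-1.66), the alcohol dehydrogenase gene Adh1 (-1.58), the protease inhibitor gene Cst3 (-1.57), Fam107a (-1.54), Slitrk6 (-1.52) and Emc7 (-1.51). Lrrc55 was at 9.78 in Men1 RIP-Cre and near 7 in the other groups, with 7.05 in wt, 7.09 in RIP-Cre, 6.97 in Rbp2 RIP-Cre and 7.08 in the double knockout. Men1 (-0.43, adjusted p = 0.0729) and Kdm5a (0.01, adjusted p = 0.963) did not pass.

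Limma called an interaction in 675 genes, 354 above and 321 below 0, with 81 left unnamed by the rule. Cyclic loess normalization gave 504, 151 above and 353 below, 358 of them shared, so the share above 0 went from 52.4% to 29.96%. With the array median held fixed 20 were called, 15 of them shared, and the median size of the 675 went from 0.77 (median SE 0.18) to 0.50 (median SE 0.18). The sex-linked difference held fixed left 7. Single arrays moved the count widely. It was 22, 85 and 44 without Men1 arrays 1, 2 and 3, and 2783 and 36 without RIP-Cre arrays 2 and 3. Without Rbp2 arrays 1, 2 and 3 it was 73, 56 and 1370, and without double-knockout arrays 1 to 4 it was 47, 1397, 55 and 1160. Called without each array in turn were 8 of the 20 named genes, namely Lrrc55, Myo7a, Gem, Eps8l2, Trim12a, Zfp868, Adh1 and Fam107a. Of the others, H2-Eb1 had an adjusted p of 0.0757 without Men1 array 1 and Slitrk6 of 0.135 without RIP-Cre array 3.

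Across genes, measured effects of Men1 loss were smaller where Rbp2 was also lost. An influence of Rbp2 cannot be told apart there from the array-wide difference from RIP-Cre. Over the 10660 genes called for Men1 loss, the effect of Men1 loss in Rbp2 knockouts had a slope of 0.194 (SE 0.147) on its effect with Rbp2 present, with r = 0.619 across genes. With genes and effects from different arrays the slope was 0.229 over 7437 to 8450 genes, and leaving out single arrays gave 0.138 to 0.294. For the 2672 genes called for Rbp2 loss, the slope of the Rbp2 effect in Men1 knockouts on that in RIP-Cre was -0.00057 (SE 0.354), with r = -0.0081 across genes and 0.0175 with different arrays over 287 to 2086 genes. Leaving out single arrays took this slope from -0.0902 without double-knockout array 2 to 0.337 without RIP-Cre array 3. The first effect of each pair carries the array-wide difference from RIP-Cre and the other does not, also when genes and effects come from different arrays. The Rbp2 effect in Men1 knockouts had a shift by level of its own, in the opposite direction. Its median was 0.13 in the lowest bin of genes by level and -0.01 in the highest, which alone could lower its slope. For the Men1 effect in Rbp2 knockouts these medians were -0.04 and 0.025. With the array median held fixed the slope for Men1 effects was 0.393.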

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

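The search for arrays apart from their group and the tests on them were chosen after the values were seen. Among 228 sets of 4 values from groups of 4 arrays, 12 held an array beyond the Dixon limit, and chance gives 11.4, since the limit picks about 1 in 20. In Rbp2 RIP-Cre, array 4 was high in Fam107a (7.70 against 7.49 to 7.52) and Apobec1 (8.95 against 8.56 to 8.62), and array 2 in Gdpd3 (9.49 against 7.41 to 7.49) and Scn3a (8.61 against 8.55 to 8.56). Array 3 was high in H2-Eb1 (8.62 against 7.27 to 7.42). Rbp2 array 1 was high in Uqcrb (10.71 against 9.82 to 9.87) and Nnat (9.55 against 8.90 to 9), low in the red blood cell mean (6.99 against 7.38 to 7.45), and had the lowest array median (7.82 against 7.96 to 7.98). Double-knockout array 2 was high in Kcnh5 (9.61 against 9.04 to 9.12) and in the early response mean (9.15 against 8.80 to 8.86), and array 1 in the lymphocyte mean (7.85 against 6.90 to 7). No array was removed for these values.

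An interaction was called in 675 genes. That count ran from 22 to 2783 without single arrays and was 20 with the array median held fixed. Of the 20 genes named here, 8 stayed called without each array in turn. The genes above 0 were H2-Eb1 (2.91), Prom1 (1.92), Myo7a (1.92), Gem (1.89), AI506816 (1.88), Eps8l2 (1.85), Trim12a (1.67), Kcnh5 (1.66), Spc25 (1.62) and Apela (1.60). Those below 0 were Lrrc55 (-2.58), Zfp868 (-1.90), Ttc30b (-1.87), Cd63 (-1.82), Tmtc3 (-1.66), Adh1 (-1.58), Cst3 (-1.57), Fam107a (-1.54), Slitrk6 (-1.52) and Emc7 (-1.51). Lists with an interaction by camera were oxidative phosphorylation (-0.56, adjusted p = 1.51e-13), beta cell genes (-0.51, adjusted p = 2.38e-07), the unfolded protein response (-0.60, adjusted p = 1.65e-05) and exocytosis and granule (-0.34, adjusted p = 0.0152), each with adjusted p = 0.626 with an estimated correlation. Cholesterol synthesis (-0.48, adjusted p = 0.000249, and adjusted p = 0.632 with an estimated correlation) was also below 0. Hox genes (0.29, adjusted p = 0.000515) and endothelial cells (-0.27, adjusted p = 0.0124) had adjusted p = 0.689 with an estimated correlation. Members called over all genes were 1 beta cell gene, 1 unfolded protein response gene and 2 exocytosis genes, all lower. Adjusted over the list alone, 8 beta cell genes were lower, oxidative phosphorylation had 1 higher and 9 lower, the unfolded protein response 1 and 10, and exocytosis 1 and 3. Hox genes had 4 higher, and cholesterol synthesis and endothelial cells had 0 of either. Over all genes the median interaction also went by level, from 0.39 in the lowest bin to -0.18 in the highest, and the mean level was 7.46 for Hox genes and 11.65 for beta cell genes. Beta cell genes (-0.07), exocytosis (0.05) and endothelial cells (-0.10) were not called after cyclic loess normalization. Holding the array median fixed left only cholesterol synthesis (-0.21) and endothelial cells (-0.30) as calls, with Hox genes at -0.03. The endothelial call ended without RIP-Cre array 2 (-0.22, adjusted p = 0.0981) and the exocytosis call without RIP-Cre array 3 (-0.24, adjusted p = 0.0788).

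Of the 13723 probe sets with no gene or several genes, 5861 were called in Men1 RIP-Cre against RIP-Cre, 1489 in Rbp2 RIP-Cre against RIP-Cre and 34 in the double knockout against Rbp2 RIP-Cre. What they measure was not analysed here.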

How the results depend on the processing

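The direction of Kdm5a depended on the setting in RIP-Cre against wt, in the double knockout against RIP-Cre and for the interaction. The comparisons that differ in Rbp2 alone are not among these. Directions of the hormones, Cdkn1b and Cdkn2c depended on the setting in the comparisons given below, where limma had called none of them. Every count against RIP-Cre also depended on the setting. The cause was not tested. The array median and the sex-linked difference lie mostly between groups (66.9% and 75.4% of their variance, against 8.504% for the acinar mean), so holding them fixed also removes differences between groups, whatever their cause. Group means rest on 3 or 4 arrays. Whether repeat numbers pair the arrays was not settled: 10 of 31 pairs with the same number had r across genes over 0.1, up to 0.449. Their median was 0.01, against -0.0054 for pairs with other numbers, which does not exclude pairing between some groups. How many pairs with other numbers had r over 0.1 was not counted, so the 10 of 31 speak neither for nor against pairing.

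With wt as the control, 1771 genes were called for Rbp2 loss and 1385 were shared by Men1 and Rbp2 loss. Ppy in Men1 RIP-Cre was at -0.22, Sst and Cdkn1b in the double knockout at -0.21 and 0.046, and the Kdm5a interaction at -0.0025. With wt and RIP-Cre pooled the counts were 6221 for Rbp2 loss, 3256 for the interaction and 5039 shared, with Ppy in Men1 RIP-Cre at -0.032 and Sst and Cdkn1b in the double knockout at -0.083 and 0.014. With only the groups compared, 1080 genes were called for Rbp2 loss and 1375 for the interaction.

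With the repeat number as a replicate block, which treats arrays as paired, the interaction had 1933 genes and Kdm5a in the double knockout against RIP-Cre was at 0.019. Without dim genes the interaction had 1400 genes, and with an intensity trend and robust variances 1198. All probe sets gave 16809 calls for Men1 loss, 10788 for the double knockout against RIP-Cre and 77 for the interaction. Another probe set put Cdkn1b at 0.49 in the double knockout.

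Quantile normalization put Kdm5a in RIP-Cre against wt at -0.00039 and Cdkn1b at -0.18 in Men1 RIP-Cre and -0.047 in Rbp2 RIP-Cre. With the acinar mean held fixed, 1478 genes were called for Rbp2 loss, 1184 were shared, and Cdkn2c in Rbp2 RIP-Cre was at -0.0029.

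With the sex-linked difference held fixed, calls were 114 for Men1 loss, 85 for Rbp2 loss, 2131 for the double knockout against RIP-Cre, 111 against Men1 RIP-Cre, 7 for the interaction and 6 shared, and the slope of Men1 effects was 0.370. Kdm5a in RIP-Cre against wt was at -0.028, Cdkn1b in Men1 RIP-Cre at -0.077, Cdkn2c in Rbp2 RIP-Cre at -0.056, Sst in the double knockout at -0.020 and beta cell genes in the double knockout against Men1 RIP-Cre at 0.11.

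Cyclic loess normalization gave 6875 calls for Men1 loss, 360 for the double knockout against Rbp2 RIP-Cre and 1301 shared. Ins2 was at -0.41, -0.44 and -0.47 in Men1 RIP-Cre, Rbp2 RIP-Cre and the double knockout, and Ppy at -0.38, -0.093 and -0.12. Cdkn1b was at -0.21 and -0.11 in the first 2, and Gcg at -0.22 and -0.44 and Sst at -0.20 and -0.51 in the last 2. Exocytosis was at -0.066 in Men1 RIP-Cre, -0.10 in Rbp2 RIP-Cre and 0.051 for the interaction, and beta cell genes at -0.045 in Rbp2 RIP-Cre.

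Holding the array median fixed left calls of 396 for Men1 loss, 42 for Rbp2 loss, 280 for the double knockout against RIP-Cre, 510 against Rbp2 RIP-Cre, 20 for the interaction and 9 shared, and the slope of Men1 effects was 0.393. Ppy was at -0.0085, Cdkn1b at -0.12 and Adam25 at 0.14 in Men1 RIP-Cre, Cdkn2c at -0.14 in Rbp2 RIP-Cre, Sst at -0.092 in the double knockout and Hox genes at -0.032 for the interaction.

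Without 3 control arrays, calls were 107 for RIP-Cre against wt, 6944 for Men1 loss, 475 for Rbp2 loss, 2892 for the double knockout against RIP-Cre, 48 for the interaction and 294 shared. In RIP-Cre against that single wt array Men1 was at -0.05, cholesterol synthesis at -0.035 and lymphocytes at 0.080. Cdkn2c in Rbp2 RIP-Cre was at -0.0475 and Sst in the double knockout at -0.015.

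Leaving out 1 array at a time gave 0 to 26 genes for RIP-Cre against wt, 6174 to 11006 for Men1 loss, 223 to 3382 for Rbp2 loss and 2371 to 7291 for the double knockout against RIP-Cre. It gave 111 to 272 for the double knockout against Men1 RIP-Cre, 109 to 272 against Rbp2 RIP-Cre, 22 to 2783 for the interaction and 122 to 2741 shared. Kdm5a ran from -0.053 to 0.10 in RIP-Cre against wt, -0.1025 to 0.0375 in the double knockout against RIP-Cre and -0.046 to 0.094 for the interaction. Gcg ran from -0.29 to 0.027 and Ppy from -0.082 to 0.40 in Men1 RIP-Cre, and Cdkn2c from -0.0475 to 0.2375 in Rbp2 RIP-Cre. In the double knockout Gcg ran from -0.0475 to 0.27, Sst from -0.11 to 0.265 and Cdkn1b from -0.0575 to 0.0425. The lymphocyte shift in RIP-Cre against wt ran from -0.46 to 0.073 and the acinar shift in the double knockout against Rbp2 RIP-Cre from -0.030 to 0.63.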

Other observations

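Genes called in comparisons that share no arrays, picked after the values were seen, give effects of each loss in both backgrounds. The genes named from them are examples, mostly outside the naming rule, and larger shared changes are left out, so no theme can be read from them. Men1 loss, with and without Rbp2, changed 178 genes in the same direction (79 higher, 99 lower) and 6 in opposite ones, where independent lists would share 64.7. Higher in both were Tceal6 (2.39 and 2.10), the imprinted genes Nnat (1.94 and 1.60) and Igf2, a growth factor (1.23 and 0.9975), the calcium sensor Vsnl1 (1.47 and 0.93), the GABA receptor gene Gabra4 (0.80 and 0.91) and the cofactor gene Lmo4 (0.67 and 0.61). Lower in both were Grb10 (-1.60 and -1.12), the pyruvate dehydrogenase kinase gene Pdk4 (-1.27 and -0.82), the lipid receptor gene Gpr119 (-1.23 and -0.73), the glucagon receptor gene Gcgr (-0.82 and -0.92) and Oxtr (-1.13 and -0.94). The number shared was 268 after cyclic loess normalization and 149 with the array median held fixed.

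Rbp2 loss, with and without Men1, changed 75 genes in the same direction (58 higher, 17 lower) and 9 in opposite ones, where 22.3 would be shared by independent lists. Higher in both were Pcp4 (1.89 and 1.87), Ccnd1 (1.24 and 1.38), Kcnk16 (1.16 and 1.84), Spc25 (0.92 and 2.54), the adhesion receptor gene Cd44 (0.79 and 1.19) and the endoderm factor gene Foxa2 (0.34 and 0.54). Lower in both were Apobec1 (-1.60 and -1.12), Gdpd3 (-1.29 and -2.84) and the matrix protein gene Reln (-0.47 and -0.92). The Gdpd3 call in Rbp2 RIP-Cre against RIP-Cre (adjusted p = 0.0487 by limma) was lost without any single array except Rbp2 array 2. On that array Gdpd3 stood at 9.49, against 7.41 to 7.49 on the other Rbp2 arrays. The neuronal genes Rit2 and Cnih2 rose with Men1 loss (1.46 and 1.44) and fell with Rbp2 loss (-0.53 and -0.47) in the comparisons with RIP-Cre. Cyclic loess normalization left 85 shared genes and the array median held fixed 16.

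The tests in this part were chosen after the results were seen, except that on the neighbours of Men1, and fits without single arrays were planned at the start but turned on these patterns afterwards. The large count for Men1 loss may come from menin, from an array-wide compression of the signal, or from acinar tissue. Between wt arrays alone, wt 2 minus the mean of wt 1 and wt 3 correlated with the Men1 effect across genes with r = 0.490, which could mean that a part of it is technical, against 0.0717 for the effect of Men1 loss in Rbp2 knockouts. A shift by level alone is argued against as the whole cause by 5448 genes kept after cyclic loess normalization. Compression cannot be told apart, since the array median, which lies mostly between groups, left 372 of the 10660 genes called when held fixed. Without Men1 array 1 the acinar difference was -0.53 and without RIP-Cre array 3 it was 0.66, yet 7757 and 6036 genes stayed called in the same direction, which argues against acinar tissue, and how much is menin stays open.

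The rise of Men1 in Rbp2 RIP-Cre may reflect Rbp2 loss, a compression of the signal, a swapped array or a shift of its chromosomal region. Men1 was still 0.68 higher with the array median held fixed (adjusted p = 0.0384 by limma). The lowest Rbp2 array lay 0.56 above the highest of the other 13, which argues against a swap. The 40 nearest genes had a median of -0.11 (SD 0.22), which argues against a regional shift. A difference in strain or allele at Men1 was not tested.

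The cell cycle list, with a shift of 0.28 in the double knockout against Rbp2 RIP-Cre and 1 of 41 genes called, may reflect dividing cells, lymphocytes, acinar tissue or compression. With an estimated correlation adjusted p = 0.251, so the shift itself is open. It was 0.26 (adjusted p = 5.19e-10 by camera) with the lymphocyte mean held fixed, which argues against lymphocytes as the whole source. Compression as the whole source is argued against by medians of all genes of at most 0.0375 in size at any level and a shift of 0.28 after cyclic loess normalization, and acinar tissue by a shift of 0.32 (adjusted p = 3.71e-17 by camera) without double-knockout array 3, where the acinar difference was -0.04. Macrophages, at 0.27 (adjusted p = 0.00199), were not tested as a source, and which cells divide was not measured.

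Genes near a targeted allele can be carried along with it. Of the 75 genes, 2 (Apobec1 and Sumf1) lay among the 200 nearest to Kdm5a, 2.67% against 0.998% of other genes, with a Fisher exact p of 0.174. Of the 178 genes 5 lay there (exact p = 0.034) although Rbp2 status does not differ in those comparisons, so the test cannot tell. Near Men1 there were 2 of the 178 (exact p = 0.700). Of 31 imprinted genes tested, 3 (Grb10, Nnat and Igf2) were called in the double knockout against Rbp2 RIP-Cre, with a Fisher exact p of 0.00597. Without the 4 seen first, 0 of 27 were called (exact p = 1), so the class as a whole is left open.

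Regrouping the arrays asked how often other splits call as many genes. For RIP-Cre against wt the real count was 0, which any split reaches, so the splits tell nothing there (9 was the highest other). For Men1 loss the real split called 10660 and the highest other 1, and 10 splits are too few. For Rbp2 loss 1 split of 35 called as many as 2672, the real one, with 1 as the highest other. In the double knockout against RIP-Cre the real 6716 stood against 3396 for a split that placed only double-knockout array 1 with the RIP-Cre arrays. Against Men1 RIP-Cre the values were 333 and 4, against Rbp2 RIP-Cre 239 and 20, and for the interaction 675 and 24 over 100 splits.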
